A study of Pimephales promelas with 338 samples.

How the data were processed

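Whole-body RNA of fathead minnow larvae was assayed with TempO-Seq after exposure for 24 h in deep-well plates. Per the labels' protocols, each exposure tested a pair of chemicals on 3 plates, larvae of a treatment on a plate were pooled after homogenisation, dead larvae were left out of the pools, and detector oligonucleotides were ligated on transcripts, amplified by PCR and sequenced with a barcode per sample. The deposited values are raw counts per probe, whole numbers that were not normalized, per the file headers and the values themselves. Base calling with bcl2fastq is named in the submitters' processing notes, without a version. The aligner, the probe sequences and the genome build are not given in the sources used here, so no coordinates are printed. The 338 count columns were matched to samples by the sample descriptions, with 0 unmatched columns, and the 14 smaller deposited tables held the same counts, with 0 cells that differed. Of the 1829 gene symbols, 1724 were found in the RefSeq gene table of the assembly fPimPro1.hap1.1, which was used for names only. The symbols cbr1, glb1 and ugdh each had a pair of probes, which were kept apart, and 4 probes had no count in any library. A probe measures a short part of its transcript, and near-identical copies of a gene may share a probe, so single genes of large families such as collagens and ribosomal proteins are uncertain to that extent.

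Groups were taken from the treatment labels and the sample descriptions, which give the chemical, the plate letter and the dose code. The titles of 26 libraries name DMSO while their treatment label says caffeine, and these were grouped as caffeine by the treatment label. One compound is called a sulfoxide in the sample labels and a sulfone in the series text, and the name of the sample labels is used. The labels give no concentration per code, and the code follows the position of the row on the library plate, D1 in the first row. The caffeine concentration is not used, since the sources do not say which of the caffeine sets their value belongs to. Replicates of a chemical are pools of different larvae from different plates. Nothing in the labels says whether the QA libraries came from separate exposures, so their p-values measure the spread between these libraries, which can be technical. The most alike pair of replicate libraries still differed by more than sampling noise, with a chi-square per degree of freedom of 1.42 in the QA set and of at least 1.59 elsewhere, so no library was treated as deposited more than once. Library totals ran from 112247 to 1029511, and no named gene was compared with a group holding 3 counts or fewer. PCR reads were counted without molecular identifiers as far as the sources used here say, so counting intervals would cover counting error only and none are given.

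Counts were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3) by the quasi-likelihood F-test after TMM normalization, with probes kept by filterByExpr at a minimum count of 10 and Benjamini-Hochberg adjustment at 0.05. Each exposure was fitted with a mean per group over all of its libraries, which share an estimate of the spread. Each of the 8 codes was compared with the DMSO libraries of the exposure, with adjustment over all genes and codes together, and a linear contrast over the codes gave the trend as log2 units per step, without the controls. Caffeine was compared with DMSO in the 36 plate controls with exposure as a term, and in the 16 QA libraries. Interaction terms tested whether the caffeine change differed between exposures or between the kinds of library, and whether the slopes of cetirizine and fexofenadine differed. Fixed gene lists with at least 5 tested members, 19 in each comparison, were tested with camera (limma) on log2 CPM with a prior count of 2, at a preset inter-gene correlation of 0.01 and with a correlation estimated from the residuals, and adjusted over the lists. The results of the lists of aryl hydrocarbon receptor, NRF2 and oxidative stress, heat shock, hypoxia, cell cycle and replication, carbohydrate and energy, glucocorticoid and clock, immediate-early, liver and plasma protein, digestive enzyme, skin, cartilage and bone, inflammation, synapse, unfolded protein and ribosomal protein genes are reported, and a list not mentioned for a comparison did not pass there with all codes included. The lists were written from general knowledge of fish and vertebrate genes, and some genes, such as vegfab, stand in more than one of them. The rule that matched symbols to lists left hsp70.3 out of the heat shock list, which had 7 members on the panel. Results of that list therefore say nothing about hsp70.3.

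The comparisons, tests, gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where a choice is said to have been made afterwards. Genes were named by rule among those with a symbol and a mean of at least 20 counts. For caffeine these were the 10 largest rises and 10 largest falls among called genes that moved the same way in at least 15 of the 18 plate pairs. For each chemical they were the 5 steepest called slopes each way and the 5 largest called changes each way at D1 and at D8, and in every comparison at most 3 called members per list by adjusted p were added. Members of lists given with their slopes beyond that number are examples of the list's count. The QA set used the genes named for the plates. Pair differences for the plot of caffeine pairs used log2(CPM + 0.5).

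The alternatives were DESeq2 1.42.0 in place of edgeR, DESeq2-style size factors in place of TMM, no filter on low counts, the plate letter as replicate block, leaving out each plate letter in turn, no exposure term for caffeine, the library plate as block for the QA set, and leaving out libraries below 0.2 of the median total of the fit. Added after seeing the data were leaving out code D1, each exposure for caffeine, gabapentin D5 replicate C, and cis-nonachlordane D6 replicate B. Since a plate letter marks libraries from the same exposure plate by the protocol, the letters pair the samples. As a check, the correlation of deviations from the group means was higher between libraries of the same letter than of different letters in each exposure. The means were 0.106 and -0.0530 for metolachlor OA and 3,4-dichlorophenyl isocyanate, 0.0388 and -0.0193 for 1(2H)-phthalazinone and gabapentin, and 0.0580 and -0.0290 for metribuzin-DA and 2-tert-butyl-4-methoxyphenol. They were 0.0726 and -0.0362 for hydrochlorothiazide and 4-chlorophenyl methyl sulfoxide, 0.0841 and -0.0420 for cetirizine and fipronil amide, and 0.0282 and -0.0141 for fexofenadine and cis-nonachlordane. The share of libraries that correlated best with their own letter ran from 75.9% to 90.7%.

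Each test was tested on simulated counts drawn from the real means, dispersions and library sizes with known sets of changed genes. For chemicals, a simulated change had its stated fold at D1 and shrank with each further code. Against DMSO (1532 genes, the gabapentin design), edgeR called 16.4% of 1.5-fold, 53.7% of 2-fold and 92.4% of 4-fold changes at some code, and for the trend 38.8%, 76.1% and 98.5%. For caffeine on the plates (1363 genes) it recovered 64.2% of 1.25-fold, 94.0% of 1.5-fold and 98.5% of 2-fold changes, and in the QA set (1324 genes) 58.2%, 89.6% and 97.0%. A caffeine change in 1 of 6 exposures was recovered in 22.4% of genes at 1.5-fold and 49.3% at 2-fold (1363 genes), a DMSO change in 1 of 6 exposures in 38.8% and 79.1% (1474 genes), a caffeine change in the QA set alone in 71.6% and 88.1% (1508 genes), and a trend for cetirizine alone in 26.9% and 61.2% (1515 genes). Joins, correlations and figures used Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and numpy 2.4.6.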

Results

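Gene expression was measured with TempO-Seq, a targeted assay in which pairs of detector oligonucleotides are ligated on their transcript and counted by sequencing, in whole larvae of the fathead minnow, Pimephales promelas. Larvae were exposed for 24 h to 12 chemicals, tested as pairs in 6 exposures, each run on 3 plates. A library was made from the pooled homogenates of a single treatment on a single plate, 5 larvae by design with dead larvae left out. Each chemical was given at 8 nominal concentrations, coded D1 to D8, over a geometric series from 66.67 to 0.021 µM. The series ran from 56.43 to 0.018 µM for fipronil amide and from 32.2 to 0.011 µM for fexofenadine. The labels do not say which end of the code is the highest concentration, so results are given by code and slopes are given per step towards D1. Every code had 3 libraries, replicates A, B and C for the 3 plates, except 2-tert-butyl-4-methoxyphenol D1, which had a single library, replicate A. The 338 libraries comprised 286 chemical libraries, 18 solvent (DMSO) and 18 caffeine libraries from the exposure plates, and a quality-assurance (QA) set of 8 DMSO and 8 caffeine libraries. The deposited table held raw counts for 1832 probes of 1829 gene symbols, and totals per library ran from 112247 to 1029511 with a median of 609598. The lowest total, in cis-nonachlordane D6 replicate B, was followed by 337162. Levels are given below as counts scaled to the library total (CPM) with the SD over libraries.

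Caffeine served as the positive control on every exposure plate, and it raised hbae5, tat and hspb8 and lowered cell cycle genes. The haemoglobin gene hbae5 rose from 74.4 ± 51.5 CPM in DMSO to 193 ± 125 CPM in caffeine (SD, n = 18 each), a log2 fold change of 1.35 ± 0.27 (SE), and was higher in 15 of 18 plate pairs. The amino acid catabolism enzyme tat rose by 0.75 ± 0.10 on the log2 scale (adjusted p = 2.3e-06) and the small heat shock protein gene hspb8 by 0.50 ± 0.05 (adjusted p = 1.11e-08), both in 18 of 18 pairs. Among falling genes, the cyclin-dependent kinase subunit cks1b went from 82.0 ± 13.3 to 52.2 ± 18.4 CPM, a log2 change of -0.69 ± 0.11, lower in 17 of 18 pairs. The fatty acid desaturase fads2 (-0.62) and elongase elovl2 (-0.58) fell in 15 and 17 of 18 pairs. These genes were named only if they moved the same way in at least 15 of 18 pairs, so the pair counts are no separate evidence.

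In the edgeR fit with exposure as a term, caffeine changed 58 of 1363 genes at an adjusted p below 0.05, 22 upwards and 36 downwards, and 228 genes had an unadjusted p below 0.05. The named risers were, besides hbae5, tat and hspb8, the cochaperone bag3 (0.48), the coagulation factor f5 (0.46), sesn1 (0.36), socs2 (0.34), csrnp1a (0.32), the glycolytic aldolase aldoaa (0.31) and cebpd (0.30). Falling genes with roles in mitosis and replication were kif14 (-0.63), cdk1 (-0.53), ccna2 (-0.52), cdca8 (-0.51), ncapd2 (-0.47), ube2c (-0.46), aspm (-0.45) and pcna (-0.35). Of the 18 tested members of the cell cycle and replication list, 7 fell and 0 rose, with 11 falling when adjusted over the list alone. That list was lowered as a group (camera, adjusted p = 2.15e-10 over 19 lists, and 0.0125 with an estimated correlation). The immediate-early and cAMP-responsive list, with 1 riser of 12 (dusp1, 0.18; 3 adjusted over the list alone), was raised as a group (adjusted p = 0.00276, and 0.0285 with an estimated correlation). The liver and plasma protein list, with 1 riser of 6 (tat; 4 adjusted over the list alone), was also raised (adjusted p = 0.00203, and 0.0285 with an estimated correlation, which became 0.0896 with the plate as replicate block). The heat shock list, with hspb8 and bag3 rising of 7 tested (2 adjusted over the list alone), passed with the preset correlation (adjusted p = 0.0124) and missed with an estimated correlation (adjusted p = 0.0900). The same held for the hypoxia list, with 0 risers of 6 and 3 adjusted over the list alone (adjusted p = 0.0242, and 0.134 with an estimated correlation). It also held for the glucocorticoid and clock list, in which bhlhe40 rose by 0.14 (1 of 11, also adjusted over the list alone), at an adjusted p of 0.0484 and, with an estimated correlation, an adjusted p of 0.249. The digestive enzyme list, in which the intestinal phosphatases alpi.1 (0.25) and alpi.2 (0.22) rose, 2 of 5 and 2 adjusted over the list alone, had an adjusted p of 0.0484 and of 0.164 with an estimated correlation. With the plate as replicate block, the glucocorticoid and digestive enzyme lists both lost their call at the preset correlation (adjusted p = 0.0552 each). Leaving out plate C of every exposure left 8 genes, dropping the exposure term left 24, and leaving out single exposures gave between 29 genes (without that of 1(2H)-phthalazinone and gabapentin) and 76 (without that of fexofenadine and cis-nonachlordane).

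**Figure D1:**
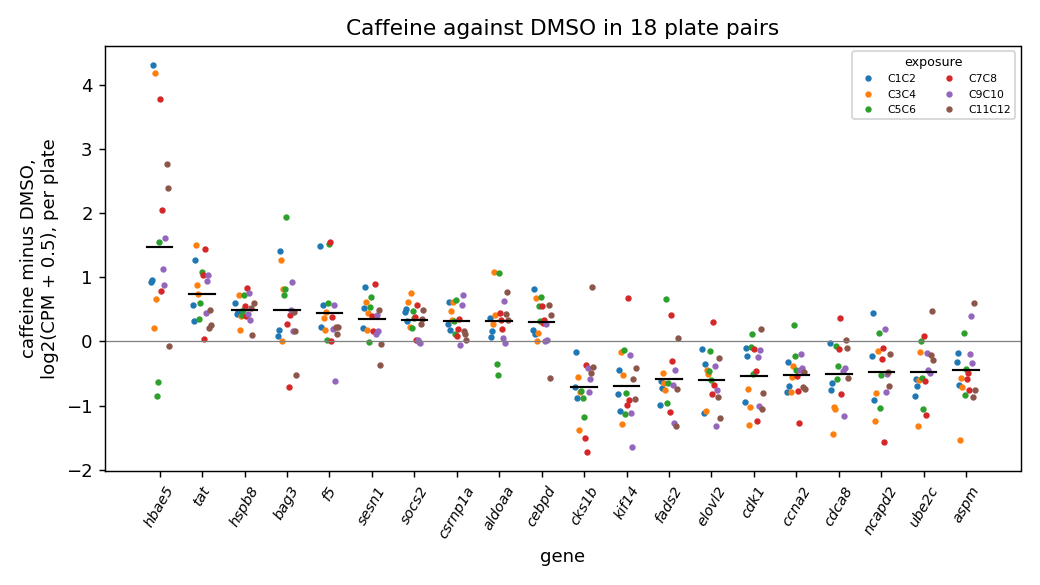
Difference between caffeine and DMSO on each of 18 plates, as log2(CPM + 0.5), for the named genes, with points coloured by exposure and horizontal bars at the mean of the 18 differences. The points of hspb8 and tat lie above 0 in 18 of 18 pairs, and those of cks1b below 0 in 17 of 18.

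Whether the caffeine change differed between the 6 exposures was tested with an interaction term, which passed in 0 of 1506 genes with edgeR and in 0 with DESeq2, with 64 genes at an unadjusted p below 0.05 and 75.3 expected by chance. The DMSO libraries themselves differed between exposures in 144 of 1474 genes, against 424 with an unadjusted p below 0.05. The endoplasmic reticulum chaperone hspa5 shared the smallest adjusted p (4.95e-05) with lims1 and rgs2, with 1149.8 ± 107 CPM (SD, n = 3) in the exposure of 1(2H)-phthalazinone and gabapentin and 3083 ± 353 CPM in that of hydrochlorothiazide and 4-chlorophenyl methyl sulfoxide. The ribosomal protein gene rpl32 went from 27913 ± 805 CPM in the exposure of fexofenadine and cis-nonachlordane to 55015 ± 3767 CPM in the exposure of metolachlor OA and 3,4-dichlorophenyl isocyanate (adjusted p = 5.58e-05). These genes were chosen after their values were seen, and the count was 13 without plate B and 85 without plate C. Library totals differed too, with a median of 485808.5 in the exposure of fexofenadine and 614714.5 in that of metolachlor OA. Wells repeated between exposures in the labels show that part of the libraries sat on other library plates. Differences from exposure, library plate and depth were not told apart. Every chemical below was compared with the libraries of its own exposure.

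In the QA libraries caffeine again raised hbae5 (1.05 ± 0.12, adjusted p = 1.02e-06), tat (0.59 ± 0.10) and aldoaa (0.49 ± 0.06) and lowered cks1b (-0.64 ± 0.15) and pcna (-0.28 ± 0.06). Further called genes among those named for the plates were alpi.2 (0.31), cebpd (0.29), socs2 (0.36), dusp1 (0.25) and socs3a (0.54). The other 16 of the 26 named genes were not called in the QA set, among them hspb8 (0.24, adjusted p = 0.0770), kif14 (0.04, adjusted p = 0.973) and alpi.1 (-0.05, adjusted p = 0.913). With the library plate as replicate block, 5 of these were called: hspb8, sesn1, fads2, elovl2 and ncapd2. The differences of hspb8, kif14 and alpi.1 from the plates, -0.27, 0.67 and -0.32, did not pass after adjustment (adjusted p = 0.994 each). The fit called 17 of 1324 genes, 12 up and 5 down, with 134 at an unadjusted p below 0.05, and 48 genes with the library plate as replicate block. Of the 19 tested members of the cell cycle list, 1 fell and 4 fell adjusted over the list alone, and the list was lowered as a group (adjusted p = 1.67e-05, and 0.00640 with an estimated correlation). The liver (adjusted p = 0.00761), heat shock (0.0316) and glucocorticoid and clock (0.0477) lists were raised with the preset correlation. With an estimated correlation their adjusted p-values were 0.0553, 0.198 and 0.198. The interaction between caffeine and the kind of library passed in 0 of 1508 genes with edgeR and in 0 with DESeq2, and 52 genes had an unadjusted p below 0.05. Over the 1317 genes tested in both, fold changes in the plates and in the QA set had r = 0.448 and rho = 0.361 across genes, which are not independent replicates. Of 57 and 17 called genes, 11 were called in both, each with the same sign, against 0.736 expected of independent lists (Fisher's exact test, p = 3.77e-12). That test treats genes as independent, so its p-value can overstate the evidence where genes move together. Of the 17 genes called in the QA set, 14 had the same sign in the plates. Among the others, hspa5 was raised in the QA set (0.32, adjusted p = 5.61e-04) and stood at -0.19 in the plates (adjusted p = 0.229), with a difference of 0.50 that did not pass (adjusted p = 0.239).

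3,4-Dichlorophenyl isocyanate raised ahrra and ahr2 and lowered collagen genes towards D1. The repressor of the aryl hydrocarbon receptor, ahrra, rose from 72.9 ± 10.3 CPM in DMSO to 3635 ± 741 CPM at D1 and 2887 ± 158 CPM at D2 (SD, n = 3 each), log2 fold changes of 5.62 ± 0.20 and 5.29 ± 0.19 (SE). The receptor gene ahr2 rose from 512 ± 28.2 to 1499.9 ± 56.0 CPM at D1, a log2 fold change of 1.55 ± 0.11. The stress-inducible chaperone hsp70.3 rose 9.20-fold at D1, from 32.5 ± 12.6 to 291 ± 86.9 CPM, and its log2 fold change at D2 was 1.30 ± 0.30. The hypertrophic cartilage collagen col10a1a fell from 2446 ± 205 to 940.2 ± 125 CPM at D1 (-1.38 ± 0.17) and by 0.66 on the log2 scale at D2.

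Against DMSO, edgeR called 64 of 1507 genes at some code: 62 at D1 (32 up, 30 down), 17 at D2 (13 up, 4 down), 4 at D3 and a single gene, ahrra, at D4 and D6. The 4 genes at D3 were ahrra (2.40), ahr2 (0.56), the glycogen phosphorylase pygl (0.60) and fkbp5 (-0.98), and these codes and genes were singled out after their values were seen. A linear trend over the codes was called for 282 genes, 121 rising and 161 falling towards D1, with 456 at an unadjusted p below 0.05 and 75.4 expected by chance. The slope of ahrra was 0.81 ± 0.02 log2 units per step (SE) and that of ahr2 0.21 ± 0.01. Other genes rising at D1 were osgn1 (1.56), mao (1.49), pygl (1.37) and the homeobox gene dlx3b (1.26). Falling at D1 were the RNA polymerase subunit polr2h (-2.18), the kinetochore gene nuf2 (-1.45), the mitotic kinase pbk (-1.33) and fgfbp2b (-1.17), which went from 1135 ± 74.8 to 503 ± 130 CPM.

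Of the 3 tested members of the list of aryl hydrocarbon receptor genes, ahrra and ahr2 rose with the trend and nqo1 had a slope of 0.03 (adjusted p = 0.385). Of 15 tested skin, cartilage and bone markers, 11 fell and 0 rose with the trend, all of them collagen genes such as col2a1a (-0.11 per step), col1a1a (-0.10), col1a2 (-0.09) and col9a1a (-0.09). The list was lowered as a group (camera, adjusted p = 1.58e-08, and 0.00505 with an estimated correlation). Of 17 tested NRF2 and oxidative stress genes, 8 rose and 0 fell, among them the peroxiredoxin prdx1 (0.14 per step), nfe2l2b (0.12) and gpx1a (0.10), and the list was raised (adjusted p = 3.79e-04, and 0.00511 with an estimated correlation). Of 20 tested cell cycle and replication genes, 8 fell and 0 rose, with mcm4 at -0.13, birc5a at -0.13 and pcna at -0.11 per step. The cell cycle list passed with the preset correlation (adjusted p = 2.94e-04) and missed with an estimated correlation (adjusted p = 0.0962). Of 5 digestive enzyme genes, alpi.1 (-0.12) and prss1 (-0.12) fell, and the list passed with the preset correlation (adjusted p = 0.00988) and missed with an estimated one (adjusted p = 0.0953). Adjusted over the list alone the counts were the same, except that 4 of the 5 digestive enzyme genes fell. Without D1, 52 trend genes and 11 genes at some code were called, ahrra kept a slope of 0.71 ± 0.02, and the skin, cartilage and bone list was still lowered with an estimated correlation (adjusted p = 0.00558), while the NRF2 list was raised with the preset correlation (adjusted p = 0.0400) and missed with an estimated one (adjusted p = 0.0695). Members passing without D1 were 5 of 15 for skin, cartilage and bone, 2 of 16 for NRF2, 1 of 20 for the cell cycle list (adjusted p = 0.0434 with the preset and 0.5258 with an estimated correlation) and, in the edgeR fit, 0 of 5 for digestive enzymes, whose list was no longer called (adjusted p = 0.389). The count at some code was 127 with the plate as replicate block, 20 without plate B and 22 without plate C, and the trend count was 86 without plate B and 166 without plate C.

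**Figure D2:**
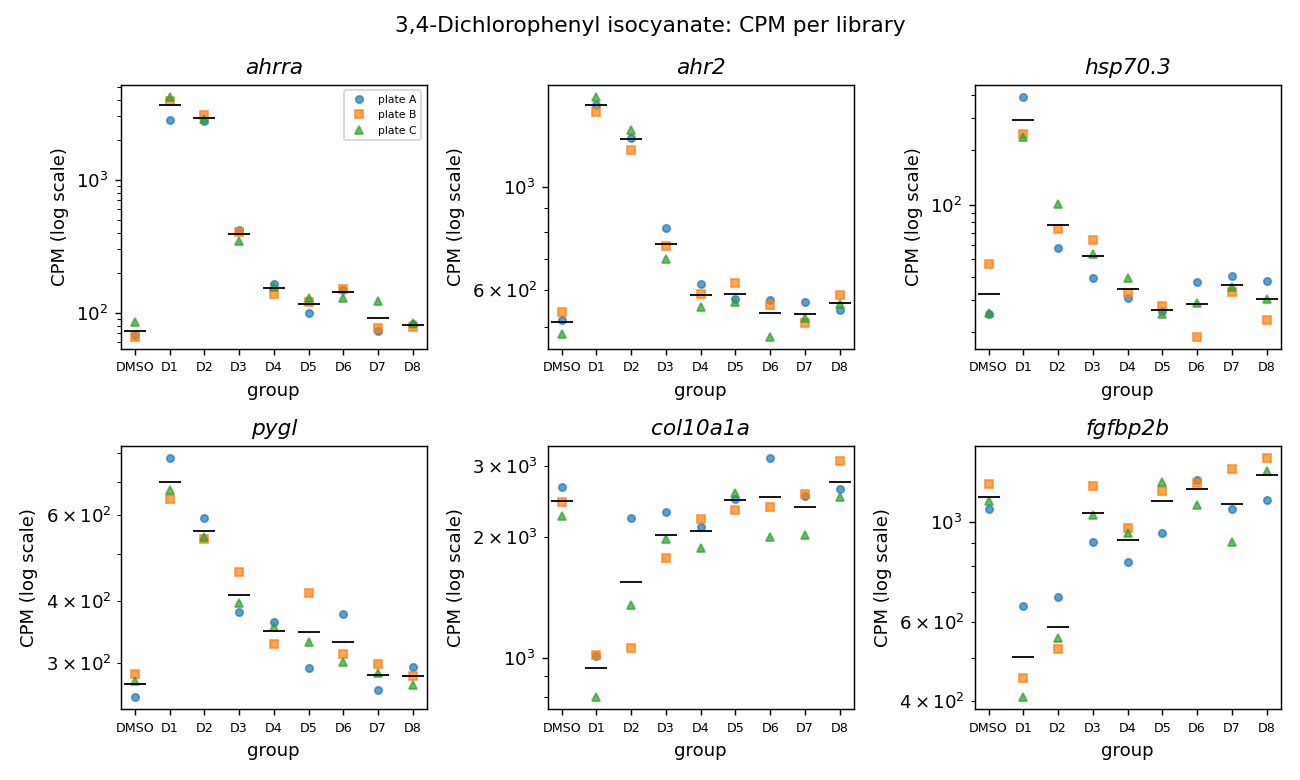
CPM on a log axis of 6 genes in DMSO and at codes D1 to D8 of 3,4-dichlorophenyl isocyanate, with points for libraries, markers for the plate and horizontal bars at the group mean. The mean of ahrra is 3635 CPM at D1 and 81.5 CPM at D8, beside 72.9 CPM in DMSO.

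2-tert-Butyl-4-methoxyphenol, also known as butylated hydroxyanisole, raised gsr, prdx1, gclc and ldha at D2, where 3 libraries were measured. The glutathione reductase gene gsr rose from 51.5 ± 20.02 CPM in DMSO to 199 ± 34.7 CPM at D2 (SD, n = 3 each), a log2 fold change of 1.95 ± 0.25 (SE), and prdx1 from 51.9 ± 7.07 to 170.5 ± 50.7 CPM (1.68 ± 0.25). The glutamate-cysteine ligase gene gclc rose from 130.6 ± 5.89 to 349 ± 54.1 CPM (1.42 ± 0.16) and lactate dehydrogenase ldha from 2197 ± 543 to 5706 ± 823 CPM (1.38 ± 0.18). In the single D1 library the same genes stood higher still, at 276 CPM for gsr, 414 for prdx1, 519 for gclc and 8945 for ldha. The intestinal phosphatase alpi.2 fell from 1228 ± 92.2 CPM in DMSO to 716 ± 28.3 CPM at D2 (-0.78 ± 0.17) and stood at 63.0 CPM in the D1 library.

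Against DMSO, 234 of 1589 genes were called at some code: 213 at D1, from a single library, 50 at D2 (36 up, 14 down), 9 at D3, 3 at D4 and acad11 (-1.82) at D6. The 3 genes at D4 were prdx1 (1.10), a probe of ugdh (0.53) and arl6ip1 (-0.65), named here after their values were seen. At D3, gsr (1.17), prdx1 (1.06), aldoaa (0.93), ldha (0.82) and gclc (0.69) were among the genes called. The trend was called for 433 genes, 229 rising and 204 falling towards D1, with 592 at an unadjusted p below 0.05. The call at D1 assumes that its single library varies like those of the other groups. Without D1, 32 genes were called at some code and 70 with a trend, and without plate A, which holds the D1 library, 22 and 47.

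Of 17 tested NRF2 and oxidative stress genes, 9 rose and 2 fell with the trend. The risers included prdx1 (0.36 per step), gsr (0.33), the cystine transporter slc7a11 (0.29) and gclc (0.28), and those falling were prdx2 (-0.05) and sod1 (-0.07). The list was raised (camera, adjusted p = 1.01e-05, and 8.44e-04 with an estimated correlation), and without D1 7 members rose and it was still raised (adjusted p = 8.00e-05 with an estimated correlation). Of 8 tested hypoxia genes, 6 rose, among them ndrg1a (0.29), slc2a1b (0.25) and vegfab (0.20; 0.77 ± 0.18 at D2), with adjusted p = 1.01e-05, and 0.00368 with an estimated correlation. Of 20 carbohydrate and energy genes, 7 rose and aldoca fell by 0.10 per step, with ldha (0.30) and aldoaa (0.27) the steepest (adjusted p = 0.00993, and 0.0428 with an estimated correlation). Without D1 the hypoxia and carbohydrate lists were still raised with an estimated correlation (adjusted p = 0.0302 and 0.0202), with 2 of 7 and 4 of 20 members rising. Of 11 inflammation and innate immunity genes, 6 rose with the trend, including il1b (0.83), mmp9 (0.48), myd88 (0.28) and socs3a (0.28), and the list was raised (adjusted p = 3.85e-04, and 0.0328 with an estimated correlation). Without D1, 0 of 10 tested members of that list rose in the edgeR fit and its adjusted p was 0.880. At D2 the log2 fold changes of mmp9 and socs3a were 1.21 ± 0.52 (adjusted p = 0.370) and 0.70 ± 0.35 (adjusted p = 0.517). The AP-1 gene fosl1a had the steepest slope (0.98 ± 0.12 per step), with 1122 CPM in the D1 library and 82.9 ± 133 CPM at D2, beside 4.63 ± 1.91 in DMSO, and ero1a, an oxidoreductase of the endoplasmic reticulum, followed at 0.66 ± 0.07.

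Of 15 tested immediate-early genes, 7 rose and 3 fell with the trend, and that list was not called (adjusted p = 0.125). Without D1, 1 of 14 rose and 1 fell. Of 5 digestive enzyme genes, 4 fell with the trend, alpi.2 (-0.38), prss1 (-0.23), amy2a (-0.18) and prss59.1 (-0.16), and the list was lowered (adjusted p = 0.00202, and 0.0428 with an estimated correlation). With the plate as replicate block the estimated-correlation value was an adjusted p of 0.0566, and without D1 it was 0.116, with 1 of 5 falling. Of 20 cell cycle and replication genes, 8 fell, with pcna at -0.21 and cdk1 at -0.17, and the list passed with the preset correlation (adjusted p = 3.85e-04) and missed with an estimated one (adjusted p = 0.131). Of 15 GABA, glutamate and synapse genes, 5 fell, such as grin1a (-0.11) and gria2a (-0.08), with an adjusted p of 0.0124 and, with an estimated correlation, an adjusted p of 0.111, or 0.0416 with the plate as replicate block. Of 15 skin, cartilage and bone markers, col10a1a (-0.13), col1a1b (-0.07) and col1a2 (-0.08) fell, at an adjusted p of 0.0424, and of 0.206 with an estimated correlation. Without D1, 3 of 20 cell cycle genes fell, 0 of 15 synapse genes fell in the edgeR fit, and 1 of 15 skin, cartilage and bone markers fell. The cell cycle (adjusted p = 5.90e-04) and synapse (adjusted p = 0.0238) lists then passed with the preset correlation and missed with an estimated one (adjusted p = 0.116 each), and the skin, cartilage and bone list did not (adjusted p = 0.203). Adjusted over the list alone, the counts were 7 risers for hypoxia, 10 falling for the cell cycle and 6 falling for the synapse list, and otherwise the same. Among the tissue markers named by the rule, the eye marker rgra (-0.09), the photoreceptor gene pde6c (-0.05) and the neuronal genes map2 (-0.08) and gap43 (-0.07) fell per step, and the fibrinogen gene fgb rose (0.15). Leaving out D1, 0 of 4 eye and photoreceptor markers and 0 of 10 neural and glial markers fell in the edgeR fit, and 2 of 7 liver and plasma protein markers rose. Without plate A, the slopes of socs3a (-0.11), gap43 (0.00874) and col1a2 (0.00116) changed sign, and of the named slopes of this chemical and 3,4-dichlorophenyl isocyanate, 39 of 124 were called without D1.

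**Figure D3:**
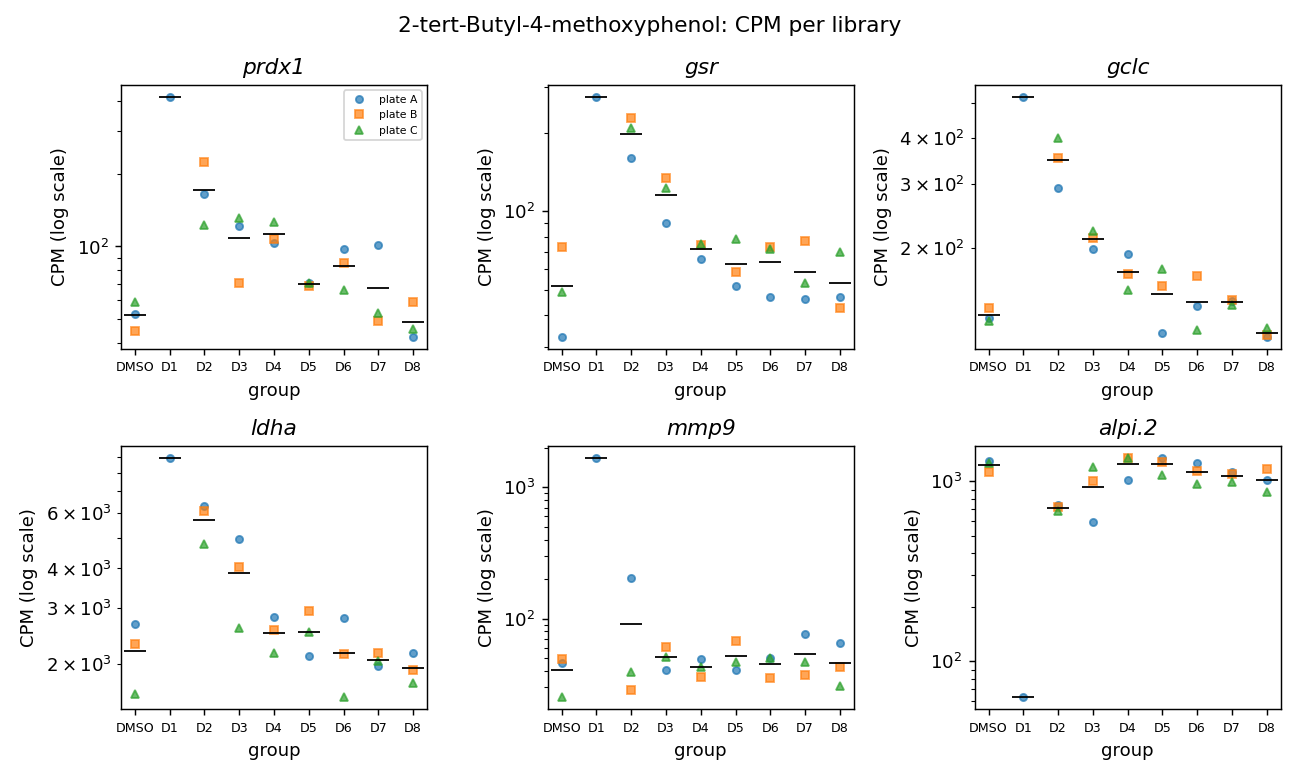
CPM on a log axis of 6 genes in DMSO and at codes D1 to D8 of 2-tert-butyl-4-methoxyphenol, with points for libraries, markers for the plate and horizontal bars at the group mean. D1 is a single point, at 414 CPM for prdx1 and 63.0 CPM for alpi.2, beside DMSO means of 51.9 and 1228 CPM.

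Metribuzin-DA changed 1 of 1589 genes in edgeR, a probe of ugdh, the enzyme that makes UDP-glucuronic acid. It rose from 1222 ± 138 CPM in DMSO to 2202 ± 198 CPM at D1 (SD, n = 3 each), a log2 fold change of 0.85 ± 0.14 (adjusted p = 0.00582), with a slope of 0.08 per step (adjusted p = 0.00891). The other probe of ugdh was not called, at any code or with a trend. With the plate as replicate block 3 genes were called at some code and 3 with a trend, and edgeR called 0 when plate A, B or C was left out. Of 17 NRF2 and oxidative stress genes 0 rose or fell, 1 rose adjusted over the list alone, and the list was raised with the preset correlation (adjusted p = 0.0125). With an estimated correlation its adjusted p was 0.0571, and 0.00900 with the plate as replicate block.

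Cetirizine, a second-generation antihistamine, had 3 of 1484 genes with a trend and 0 called against DMSO at any code in edgeR and 0 in DESeq2. The glutathione reductase gsr rose by 0.11 ± 0.02 per step towards D1, and gale (-0.12 ± 0.03) and the lysyl-tRNA synthetase kars1 (-0.10 ± 0.02) fell, each at an adjusted p of 0.0427. The trend passed in 101 genes at an unadjusted p below 0.05, and leaving out each plate in turn left 0 or 1 genes. The NRF2 list, with gsr rising of 17 tested and 3 rising adjusted over the list alone, was raised (adjusted p = 0.0251, and 0.0280 with an estimated correlation, or 0.0512 with the plate as replicate block). Fexofenadine, another antihistamine, was tested in a different exposure and over a different concentration series. It had 0 of 1471 genes with a trend in edgeR and in DESeq2, with 109 at an unadjusted p below 0.05. A single gene, mmp9, was lower at D5 (-2.03, adjusted p = 0.0443), which was noted after its values were seen, and it was not called with the plate as replicate block, when plate A, B or C was left out, or without cis-nonachlordane D6 replicate B, which shares the fit. The difference in slope between the antihistamines, over concentration series that differ, passed in 0 of 1515 genes in edgeR and in DESeq2, with 74 genes at an unadjusted p below 0.05. For gsr the slopes were 0.11 for cetirizine and 0.01 for fexofenadine, a difference of 0.10 (95% interval 0.03 to 0.16, adjusted p = 0.757). For gale the difference was -0.11 (-0.19 to -0.02, adjusted p = 0.844) and for kars1 -0.08 (-0.15 to -0.02, adjusted p = 0.923). These genes were those with a trend for cetirizine, and the intervals are not adjusted for that choice.

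No gene was called for the other chemicals in the edgeR fits, either at some code or with a trend. Caffeine, the positive control, was called in few genes within single exposures too. It had 0 genes in the exposures of metolachlor OA, gabapentin, metribuzin-DA and cetirizine, 1 in that of hydrochlorothiazide and 2 in that of fexofenadine. A count of 0 therefore does not show that a chemical had no effect. The numbers of genes with an unadjusted trend p below 0.05 were 49 of 1507 for metolachlor OA, 96 of 1532 for 1(2H)-phthalazinone, 47 of 1532 for gabapentin, 75 of 1531 for 4-chlorophenyl methyl sulfoxide and 53 of 1531 for hydrochlorothiazide. They were 94 of 1484 for fipronil amide and 97 of 1471 for cis-nonachlordane. DESeq2 called 2 genes at some code for fipronil amide, 1 for cis-nonachlordane and 0 for the rest, and its trend counts were 0. For 1(2H)-phthalazinone, with 0 genes called, the unfolded protein (adjusted p = 0.0306) and cell cycle (0.0324) lists were lowered and the synapse list (0.0324) raised with the preset correlation, and each had an adjusted p of 0.410 with an estimated correlation. For cis-nonachlordane the ribosomal protein list was lowered with the preset correlation (adjusted p = 0.0155, and 0.924 with an estimated correlation). The library of gabapentin D5 replicate C stood apart from the other libraries of its exposure, with 136 of 1532 probes beyond 5 median absolute deviations from the median of the other libraries, against at most 5 in any other library. Without it, the counts of both chemicals of that exposure stayed at 0. Simulated data with the design of gabapentin against DMSO held changes with a stated fold at D1 that shrank with each further code. Of 2-fold and 4-fold changes, 53.7% and 92.4% were called at some code, and 76.1% and 98.5% with a trend. Of 1.5-fold changes, 16.4% were called at some code and 38.8% with a trend, so many changes of that size would be missed. Changes confined to other codes were not simulated.

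**Figure D4:**
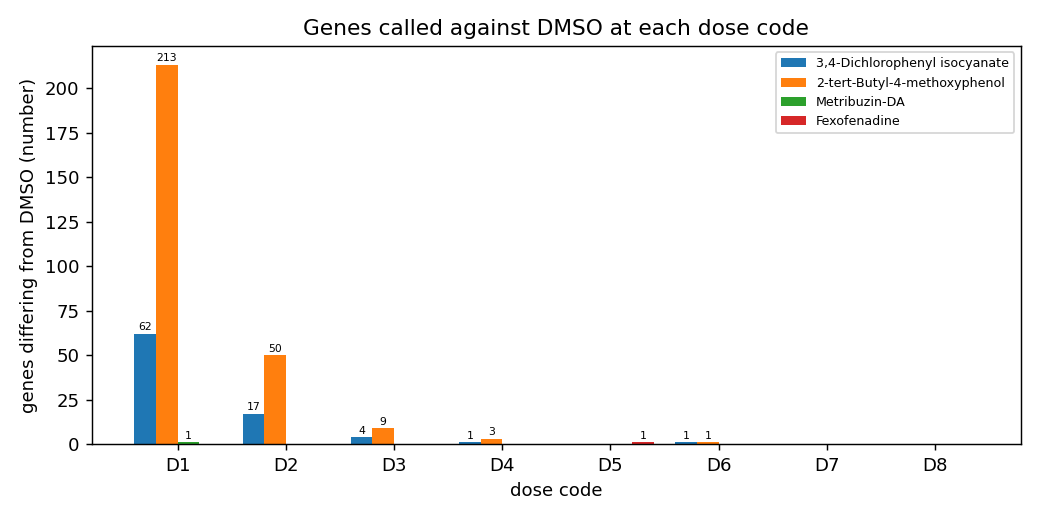
Number of genes differing from DMSO at each dose code for the chemicals with any call. 3,4-Dichlorophenyl isocyanate has 62 genes at D1 and 17 at D2, and 2-tert-butyl-4-methoxyphenol 213 at D1, from a single library, and 50 at D2.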

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

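The test behind this part was planned, and none was added later. In groups of 8 libraries, the QA sets, each named caffeine gene and the library totals were checked for a library whose gap to its nearest neighbour took up an unusual share of the whole range (Dixon's 95% limit), and 2 of 54 sets of values passed, where chance alone passes about 1 in 20. Caffeine QA replicate 7 had 640.0 CPM of the cytokine signalling suppressor socs2, with the nearest library at 553 CPM and the lowest at 479.6 CPM. Caffeine QA replicate 1 had 1890.0 CPM of the intestinal phosphatase alpi.2, with the nearest library at 1648 CPM and the lowest at 1432 CPM. No explanation of these values was tested.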

How the results depend on the processing

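Leaving out code D1, each exposure in turn, and the libraries gabapentin D5 replicate C and cis-nonachlordane D6 replicate B were alternatives chosen after seeing the data, and the rest were set beforehand. For 3,4-dichlorophenyl isocyanate, the genes at some code (64) became 127 with the plate as replicate block, 20 to 52 without single plates and 11 without D1, and the trend genes (282) became 86 to 239 and 52. For 2-tert-butyl-4-methoxyphenol, 234 became 22 to 189 without single plates and 32 without D1, and 433 became 47 to 366 and 70, with the lowest values without plate A, which holds the only D1 library. For metribuzin-DA, the single gene at some code and the single trend gene became 3 and 3 with the block and 0 without single plates, and DESeq2 called 2 trend genes. Cetirizine's 3 trend genes became 0 to 1 without single plates. Fexofenadine's single gene became 0 with the block, 0 without single plates and 0 without cis-nonachlordane D6 replicate B. From 0 genes at some code, fipronil amide rose to 2 with DESeq2, and cis-nonachlordane to 1 with DESeq2, 1 without the count filter and 0 to 1 without single plates. The 58 caffeine genes of the plates became 8 to 54 without single plates, 24 without the exposure term and 29 to 76 without single exposures (38 without that of metolachlor OA, 29 without that of gabapentin). The 17 QA genes became 48 with the library plate as replicate block, and the 144 genes between DMSO groups became 13 to 103 without single plates. The cause of these shifts was not tested. With an estimated correlation, lists past the threshold went from 7 to 3 for caffeine on the plates, 4 to 1 in the QA set, 4 to 2 for 3,4-dichlorophenyl isocyanate, 8 to 5 for 2-tert-butyl-4-methoxyphenol, 3 to 0 for 1(2H)-phthalazinone, 1 to 0 for metribuzin-DA and 1 to 0 for cis-nonachlordane. Without D1, 5 lists passed for 3,4-dichlorophenyl isocyanate and 9 for 2-tert-butyl-4-methoxyphenol with the preset correlation, and 1 and 3 with an estimated one. Those passing without D1 alone, at the preset correlation, were the p53 and ribosomal protein lists for the former and the unfolded protein, sterol and ribosomal protein lists for the latter.

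All other counts stayed within 1.5 times of the value reported under the size factors, filter, DESeq2 and block alternatives, and the block changed no other call of a count or list than those given here and beside the results. Among named genes, 128 of 128 slopes and 69 of 69 D1 changes were called with the other size factors and with the block, DESeq2 lost 5 slopes and 1 D1 change, and no filter lost 3 slopes. Slopes called were 55 of 127 without plate A, 93 of 128 without B, 106 of 128 without C and 39 of 124 without D1, and D1 changes 12 of 22, 49 of 69 and 54 of 69 without A, B and C. In the QA set, the block added calls for 5 of 26 named genes. Of the 26 named caffeine genes of the plates, 26 were called with DESeq2, with the other size factors, without the filter and with the block, 6 without plate C and 13 without the exposure term. For 2-tert-butyl-4-methoxyphenol, slopes changed sign without plate A, which holds the only D1 library, and over single plates left out ran as follows: hspb8 -0.00937 to 0.149, hmgcra -0.000597 to 0.142, npc1 -0.0207 to 0.0949, junba -0.0481 to 0.347, jun -0.0468 to 0.173, dio1 -0.12 to 0.0628, gap43 -0.0758 to 0.00874, grk1a -0.0853 to 0.0344, col1a2 -0.0882 to 0.00116, socs3a -0.109 to 0.313 and rplp0 -0.0136 to 0.069. Without D1 the sign changed for jun -0.00682, dio1 0.0462 and grk1a 0.00444. No library lay below 0.2 of the median total of its fit, the lowest being 112247 against a median of 485808.5, so that alternative gave no values. Of simulated changes that were 1.5-fold at D1, 16.4% were called at some code, and a code with a single library rests on the spread of the other groups.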

Other observations

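The comparison of trends between chemicals and the tests of the single D1 library, of plate rows and of gabapentin D5 replicate C were chosen after the results were seen, and the counts over other splits of the samples were planned. 3,4-Dichlorophenyl isocyanate and 2-tert-butyl-4-methoxyphenol, tested in different exposures with no library in common, shared part of their trend genes. Of 119 and 217 rising genes among 1501 tested in both, 57 were shared, against 17.2 expected of independent lists (Fisher's exact test, p = 3.53e-20). Of 160 and 198 falling genes, 58 were shared, against 21.1 expected (Fisher's exact test, p = 1.39e-15). Genes moving in opposite directions numbered 9 and 7, against 15.7 and 23.1 expected. Fisher's test treats genes as independent, so its p-values can overstate the evidence where genes move together. Most trend genes of both chemicals were not called without D1, a single library for 2-tert-butyl-4-methoxyphenol, and the overlap was not counted without it. The slopes of the chemicals had r = 0.388 and rho = 0.364 across genes, which are not independent replicates. Shared risers included the NRF2 list members prdx1 (0.14 and 0.36 per step), gpx1a (0.10 and 0.12) and gsr (0.10 and 0.33), and hsp70.3 (0.37 and 0.55) and ahrra (0.81 and 0.16). Shared falling genes included pcna (-0.11 and -0.21), birc5a (-0.13 and -0.12), col10a1a (-0.18 and -0.13) and fkbp5 (-0.11 and -0.34).

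Most calls for 2-tert-butyl-4-methoxyphenol rest on its single D1 library. Its total of 533797 counts lay above the lowest of the other libraries of the exposure (480606), which argues against low depth. An aberrant library unrelated to the dose series would not share its change with neighbouring doses. Across genes, its change had r = 0.210 with that of the D2 libraries from the other plates, above the highest value of the 10 chemicals with few trend genes, 0.115, and a part private to this library stays open. Larvae dying at D1 on the other plates, or damage in those pooled, may also contribute, which was not tested, and without D1 70 trend genes were called.

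The dose code follows the row of the library plate for every chemical, so a row effect would look like a trend. The other 10 chemicals were laid out over the same rows, and their highest trend count was 3 genes, against 282 and 433. This argues against the rows as the cause of the trends, and concentration stays the open explanation.

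Gabapentin D5 replicate C stood apart with 34 probes far above and 102 far below the other libraries. Its total of 670846 counts lay above the lowest of the others (490562), which argues against low depth. At these 136 probes its log2 deviations had a median size of 1.35, while the mean of replicates A and B, taken in its direction, had a median of -0.0720 (median absolute deviation 0.148), which argues against an effect of gabapentin at D5. The log2 deviations of its 19 ribosomal protein and translation genes had an SD of 0.988, against at most 0.432 in any other library, and ran from -2.24 for rpl6 to 2.05 for rplp0. This argues against a shift of that gene group as a whole. Other gene groups were not examined, so a shift of those stays open. A candidate explanation that stays open and untested is a difference in probe ligation or sequence in that pool.

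Each count was set beside 100 splits of the same libraries, the real one included. The real 3,4-dichlorophenyl isocyanate counts of 64 and 282 were reached by 1 split each, the real one, with 16 and 19 the highest of the others. Those of 2-tert-butyl-4-methoxyphenol, 234 and 433, were reached by 1 each, with 202 and 317 the highest others. For its codes, 83 other splits had calls. These counts rest mostly on the single D1 library, and every split keeps a group of 1 library. A single unusual library in that group could give the same ranking, so the splits do not decide on chance for this chemical. Fewer than 5 in 100 of these splits reached the counts of 3,4-dichlorophenyl isocyanate. The same held for the 58 caffeine genes of the plates (1 split, highest other 2) and the 144 between DMSO groups (1 split, highest other 18). For the chemical and for caffeine, these splits break the pairing by plate letter, so they do not exclude chance by themselves. Splits that keep the pairing are given below, and none were drawn for the DMSO groups. The 17 genes of the QA set were reached by 1 split (highest other 2). If the QA libraries repeat the same pools, this shows only that the pools differed beyond technical spread. Chance is not excluded for the single gene of metribuzin-DA at some code (5 splits, highest other 3) and with a trend (5 splits, highest other 2), nor for that of fexofenadine (18 splits, highest other 3). Where the real count was 0, 100 of 100 splits were as large by definition, which tests nothing. The highest others there were 1 (fexofenadine trend), 4 (cetirizine codes), 3 (caffeine between exposures), 1 (caffeine between kinds of library) and 2 (antihistamine slopes). For genes at some code and with a trend, the highest others were 6 and 122 for metolachlor OA, 0 and 1 for 1(2H)-phthalazinone, 343 and 77 for gabapentin, 1 and 4 for 4-chlorophenyl methyl sulfoxide, 2 and 32 for hydrochlorothiazide, 11 and 2 for fipronil amide and 2 and 1 for cis-nonachlordane. The splits with many genes for gabapentin, metolachlor OA and hydrochlorothiazide point to a structure of those libraries, and what drives these few splits was not tested. With splits drawn within plate letters, which keep the pairing, the real count was reached by 2 splits for the codes of 3,4-dichlorophenyl isocyanate (highest other 311) and by 1 for its trend (highest other 43). It was reached by 1 each for 2-tert-butyl-4-methoxyphenol (205 and 403), by 1 for caffeine (17) and for the cetirizine trend (1), by 4 each for metribuzin-DA (1 and 2) and by 17 for fexofenadine. Without that restriction, the 3 trend genes of cetirizine were reached by 2 of 100 splits, the real one included, with 10 the highest other. The level set was fewer than 5 in 100, so the verdict for metribuzin-DA turned between 5 and 4 splits. That is too close to exclude chance for a single gene, which was also not called when any plate was left out.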
